A study of Mus musculus with 30 samples.

How the data were processed

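Nascent RNA was measured by TT-seq in mouse E14 embryonic stem cells. In TT-seq, cells take up 4-thiouridine for a short pulse, here 5 min per the labels' protocols, and the labelled fragments are purified and sequenced. The reads therefore weight newly made RNA, introns included. The series holds 30 libraries. The cells carry an auxin-inducible degron on SPT16, a subunit of the histone chaperone FACT, or are untagged parental cells. The auxin 3-indole-acetic acid (IAA, 500 nM per the labels) triggers degradation of the tagged protein, and ethanol (EtOH) is the vehicle. The time course has 22 libraries in 11 groups of 2: untagged cells at 0 h and after IAA for 3, 6 and 12 h, and SPT16-AID cells at 0 h, after EtOH for 3, 6 and 12 h and after IAA for 3, 6 and 12 h. The washout experiment has 8 libraries: 12 h of IAA or EtOH followed by 24 h without it, in 2 SPT16-AID lines named 10E and 11D, with 2 libraries per line and treatment. Groups follow the sample titles. For many time-course libraries the labels' tag and treatment fields contradict the titles, the IAA washout libraries also carry the text of the ethanol treatment, and the labels' treatment protocol gives 24 h of treatment, so the time-course groups rest on the titles alone. The washout titles name Clone1 and Clone2, as those of the time course do, but the labels do not say which of these is line 10E or 11D.

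The washout values are raw counts of read pairs per gene, which the authors deposited as a table of 55291 genes by 8 libraries. Per the file headers, the counts were made with featureCounts 2.0.1 over whole gene features, summed by gene name, on the reverse strand, for pairs with both ends mapped. The submitters' processing notes name STAR, deepTools and the mm10 build, with no versions of the tools. Because whole genes were counted, intronic reads are included, and genes that overlap on the same strand are uncertain. Genes in near-identical copies (Usp17l, Zscan4, Hspa1a and Hspa1b, histones, ribosomal protein genes) are uncertain for that reason, since the treatment of multi-mapping pairs can divide or drop their reads. Their values are of the name as counted. The time-course values come from 16 of 17 comparison tables that the authors deposited, 1 per time point for each of 4 classes: genes, PROMPTs (transcripts upstream of promoters), eRNAs (enhancer transcripts) and DHSs (DNase-hypersensitive sites). The remaining table covers the washout. They give log2 fold changes and their standard errors, which the authors' tables hold in a form shrunken toward 0, as the values themselves show. They also give a p-value and an adjusted p-value per feature, made by the authors, and a mean normalised count over libraries, likewise the authors' own. The column names are those of a DESeq2 results table, and no version is given in the sources used here. The sources do not state which groups each time-course table compares, or in which direction. Changes there are called positive or negative as signed in the tables, without saying which cells were higher, and no per-library value, SD or n of the time course can be given. The tables give no coordinates for PROMPTs, eRNAs and DHSs.

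Coordinates are mm10, 1-based, from the count table and the GENCODE M21 annotation. Of the 55291 names, 53292 (96.4%) matched the annotation, and 99.3% of these had the same coordinates. Exonic share of a gene body was computed from that annotation.

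The count totals per library were 11068135 and 16506431 (10E EtOH), 6547992 and 10905115 (10E IAA), 15273270 and 16554314 (11D EtOH), and 10501187 and 10978586 (11D IAA). No pair of libraries of the same treatment matched within sampling noise: chi-square per degree of freedom over genes ran from 12.2 to 64.9. Apart from the line names, the labels do not say that replicates came from separate cultures, so p-values measure the spread between these libraries. Intervals on shares of counts are 95% exact binomial (Clopper-Pearson) intervals and cover counting error only.

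The washout comparison used edgeR 4.0.16 (quasi-likelihood test, robust, two-sided) in R 4.3.3 on the counts, with TMM scaling, filterByExpr and a Benjamini-Hochberg false discovery rate (FDR) of 0.05. CPM values use TMM-scaled library sizes. The 4 IAA libraries were set against the 4 EtOH libraries without a block. The same lines appear in both treatments, so line pairs the samples by design, and the fit with line as a block was an alternative. The labels do not say whether replicate numbers within a line pair libraries, so these entered a block only as an alternative. The line-by-treatment interaction was tested with edgeR, with DESeq2 1.42.0 as the alternative. A total of 28 gene lists was fixed, of which 27 had 3 or more tested members. They were tested with limma 3.58.1 camera (preset correlation 0.01, two-sided, Benjamini-Hochberg over lists), with an estimated correlation and fry beside it. In the time-course tables the lists were tested with cameraPR on the signed normal score of the authors' p-value. No correlation between genes can be estimated there without libraries. In the washout the 7 list calls became 0 with an estimated correlation, so the cameraPR p-values of the time course can be too small. Calls of the 12 h table were carried to the washout as 2 lists (camera) and as overlaps per direction (Fisher's exact test, two-sided).

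The genes named follow a rule: FACT subunits and core pluripotency factors always. In the washout, the 6 highest and 6 lowest log2 fold changes past the FDR with a mean logCPM of at least 2 and the same direction in both lines were added. For each gene table the 5 highest and 5 lowest past adjusted p 0.05 with a mean count of at least 100 were taken. For each noncoding table the rule took 2 and 2 with a mean count of at least 50. Up to 4 members of each list past its test and 2 of each other list were added by adjusted p. Predicted genes, clone names, pseudogenes, histone genes and mitochondrial genes were left out of the top and bottom sets. A few genes that the rule picks are not reported here. Groups, tests, lists, this rule and most alternatives were set before the data were examined.

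Alternatives were RLE size factors, library totals without TMM, no filter, a filter of CPM 1 in 4 libraries, line and line with replicate number as blocks, each library left out, each line alone, DESeq2, FDR 0.01 and 0.1, mitochondrial and ribosomal RNA genes left out, and for the tables adjusted p 0.01, a change of at least 2-fold, a mean count of at least 10 or 100 and cameraPR on ranks. Chosen after seeing the data were the removal of 10 loci with ribosomal RNA-like reads, the removal of both EtOH libraries numbered 1, and fry with the line block. Simulated data with 200 changed genes among 15110 tested the steps. For washout IAA against EtOH, edgeR recovered 1.49, 47.8 and 89.4% of genes changed by log2 0.5, 1 and 2, and 12 of its 104 calls (11.5%) were false, above the nominal 5%. DESeq2 recovered 7.46, 56.7 and 92.4%, with 36 of 140 calls (25.7%) false. The edgeR interaction test recovered 0, 0 and 19.7% for line by treatment, with 4 of 17 calls false. The list tests found 2 of 2 shifted lists, and of 20 unshifted lists fry called 1 and camera and cameraPR 0. Genes were simulated independently of each other. These list counts therefore do not tell how often the tests call unshifted lists of correlated genes. Sox2 lies within Sox2ot on the same strand and has 0 counts in all 8 libraries, so it is not analysed in the washout.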

Results

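TT-seq read totals of the 8 washout libraries ran from 6547992 to 16554314 counts over 55291 genes. EtOH libraries held 14.9 ± 2.59 M counts and IAA libraries 9.73 ± 2.13 M (SD, n = 4 each, two-sided exact permutation p = 0.0286, the smallest that 4 against 4 allows). The 18S ribosomal RNA locus CT010467.1 took 7.85% ± 1.63 of counts in EtOH and 26.2% ± 3.88 in IAA libraries (SD, n = 4, exact permutation p = 0.0286). Together with 9 further loci that hold ribosomal RNA-like reads, a set chosen after values were seen, the shares were 9.85% ± 2.03 and 38.5% ± 5.30 (exact permutation p = 0.0286). Outside these 10 loci the depth was 13.4 ± 2.47 M in EtOH and 6.0 ± 1.46 M in IAA libraries. Mitochondrially encoded genes held 0.300% ± 0.0499 and 0.213% ± 0.110 of counts (exact permutation p = 0.257). On the principal component with 49.1% of variance the IAA libraries of line 10E lay at 71.3 and 64.8 and those of line 11D at 21.1 and 13.8, with EtOH libraries all below 0. On the next (20.2%), the EtOH libraries numbered 1 lay at 44.8 (10E) and 40.8 (11D), apart from those numbered 2 at −18.7 and −21.0.

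The time course asks how nascent transcription changes while SPT16 is being lost, from 3 to 12 h. The leading genes given for each table are those with a mean count of at least 100, predicted genes aside, so genes with lower counts can lie further out. At 12 h Dkk1, a secreted Wnt antagonist, stood at 4.52 ± 0.52 (shrunken log2 fold change ± SE, adjusted p = 4.76e-16) in the authors' deposited table. There Id2, an inhibitor of differentiation-promoting basic helix-loop-helix factors, was at 4.47 ± 0.38 (adjusted p = 1.08e-28) and Ccn2, a matricellular growth factor, at 3.57 ± 0.39 (adjusted p = 1.83e-17). The next positive genes with a mean count of at least 100 in the authors' deposited table were Cyp1b1, a cytochrome P450 (3.42 ± 0.75), and Tmem156 (3.17 ± 0.31). Its most negative genes with a mean count of at least 100 were the mitochondrial carrier Slc25a18 (−3.50 ± 0.51, adjusted p = 3e-10), Zc3h6 (−2.57), Il4i1, an amino acid oxidase (−2.55), Chac1, which degrades glutathione (−2.55 ± 0.63), and Nprl3, a subunit of the GATOR1 complex (−2.51). In all, 1366 genes were positive and 1932 negative among 15917 with an adjusted p in the authors' deposited table at 12 h. The positive genes had a median exonic share of 23.4% and a length of 18.3 kb, the negative ones 11.1% and 49 kb, and uncalled genes 17.9% and 23.1 kb.

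Of 30 genes of the naive pluripotency network 12 were negative and 0 positive at 12 h (12 and 0 adjusted over the list alone, median −0.29, cameraPR adjusted p = 0.000126), and of 6 core factors 3 were negative, also 3 adjusted over the list alone (cameraPR adjusted p = 0.00141). In the authors' deposited table the orphan nuclear receptor Esrrb was at −2.05 ± 0.35 (adjusted p = 2.47e-08), Zfp42, known as Rex1, at −1.85 ± 0.25 (adjusted p = 9.51e-12), Tet2, a 5-methylcytosine oxidase, at −1.37, Tbx3 at −1.15 and Nanog at −0.77 ± 0.34 (adjusted p = 0.0284). Sox2 (−0.48, adjusted p = 0.237), Klf4 (−0.24, adjusted p = 0.501) and Pou5f1 (0.12, adjusted p = 0.777) did not pass in the authors' deposited table, nor did the FACT genes Supt16 (0.06, adjusted p = 0.892) and Ssrp1 (0.03, adjusted p = 0.949), whose RNA the degron does not target. Zfp42 was already negative at 6 h (−0.83 ± 0.22, adjusted p = 0.00221), whereas Esrrb was at −0.59 (adjusted p = 0.113) in the authors' deposited table.

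Immediate early genes, which respond within minutes to growth and stress signals, were positive at 12 h in 10 of 22 cases and negative in 0 (10 and 0 adjusted over the list alone, median 0.47, cameraPR adjusted p = 1.33e-06). The AP-1 subunits Fos (3.14) and Jun (2.56) and the stress factor Atf3 (1.69) passed in the authors' deposited table. Of 21 genes of the integrated stress response, the programme of amino acid shortage, 5 were negative and 0 positive (6 and 1 adjusted over the list alone, cameraPR adjusted p = 0.00502). They included the serine synthesis enzyme Phgdh (−1.39), the proline synthesis enzyme Aldh18a1 (−1.12) and the asparagine synthetase Asns (−0.89) in the authors' deposited table. Germline genes had 4 of 18 members positive (4 adjusted over the list alone, cameraPR adjusted p = 0.0364, and 0.0742 with a mean count of at least 10). They were Taf7l (2.20), Sycp3 of the synaptonemal complex (1.85), Tdrkh (1.04) and the germ cell helicase Ddx4 (0.90) in the authors' deposited table. Genes of the 2-cell-like state, a rare state resembling the cleavage-stage embryo, had 2 of 19 positive (0 adjusted over the list alone, cameraPR adjusted p = 0.00832): Usp17lb (1.5, adjusted p = 0.0411) and Zscan4c (1.29, adjusted p = 0.0456) in the authors' deposited table. Replication-dependent histone genes had 2 of 64 negative (0 adjusted over the list alone, median −0.27, cameraPR adjusted p = 0.00502), H2bc22 (−1.01) and H3c15 (−0.99) in the authors' deposited table.

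At 12 h the other 20 lists did not pass cameraPR (adjusted p from 0.0619 to 0.985). Formative and primed genes had 5 positive and 0 negative calls of 22, p53 targets 7 and 4 of 26, histone chaperones and elongation factors 2 and 6 of 26, neural markers 4 and 1 of 15 and primitive endoderm markers 2 and 3 of 18. ERK feedback genes had 1 and 3 of 12, heat shock genes 3 and 1 of 14, G1/S genes 0 and 4 of 21, G2/M genes 0 and 2 of 20, Wnt targets 4 and 0 of 19, Hox genes 4 and 0 of 30 and LIF/STAT3 targets 2 and 2 of 14. Of their members, in the authors' deposited table, the stress chaperone gene Hspa1a (4.27), the death receptor Fas (3.25), Sox3 (3.13), the Wnt ligand Wnt3 (2.91), the Nodal antagonist Lefty1 (2.75), the VEGF receptor Kdr (2.27), Hoxb9 (2.10) and the p53 target Pmaip1 (2.05) were positive. So were Hspa1b (3.12), Junb (2.48), the neural markers Sox11 (2.07) and Nes (0.81), Gata2 (1.95), Dab2 (1.72), Phlda1 (1.69), Sp5 (1.33) and Hoxc13 (1.29) in the authors' deposited table. The chromatin remodellers Chd2 (−1.71) and Atrx (−1.22), the ERK-responsive factor Etv5 (−1.36) and Rps15a (−0.96) were negative there, as were Hnf4a (−1.37), the cell cycle genes E2f2 (−1.29), Cdk1 (−0.93), Bub1b (−0.78) and Mcm10 (−0.69), Tead4 (−1.19), Nfe2l2 (−0.81) and Klf5 (−0.70).

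Fewer genes were called at the earlier times, 58 positive and 5 negative at 3 h among 10920 genes and 214 positive and 174 negative at 6 h among 12534, per the authors' deposited tables. At 3 h, Cd44, a hyaluronan receptor (1.55 ± 0.33, adjusted p = 0.000652), and Aqp3, a water and glycerol channel (1.20 ± 0.22, adjusted p = 4.83e-05), led the genes with a mean count of at least 100 on the positive side of the authors' deposited table, with the chaperone Hsp90ab1 (1.16), Maged1 (1.14) and Pik3r3 (1.1). The 5 negative genes were the cadherin Cdh3 (−1.36), Nrp2 (−0.86), St8sia6 (−0.85), Sox13 (−0.76) and Ldlrad3 (−0.60) in the authors' deposited table. Of these 1, Cdh3, was already negative at 0 h (−1.63, adjusted p = 7.41e-08) in the authors' deposited table (0.0151 expected of independent lists, odds ratio 84.3, Fisher's exact adjusted p = 0.03). Genes in the highest of 5 equal bins of exonic share had 84.7% positive signs at 3 h and those in the lowest 17%, over all genes of the table. Heat shock genes were positive in 3 of 14 cases (3 adjusted over the list alone, cameraPR adjusted p = 4.71e-07), which were Hsp90ab1, Hsp90aa1 (1.02) and Hspb1 (0.91) in the authors' deposited table. Ribosomal protein genes had 0 of 79 called and 29 positive adjusted over the list alone, with 71 positive signs (median 0.12, cameraPR adjusted p = 3.05e-21). The smallest adjusted p was that of Rpl4 (0.90, adjusted p = 0.0624) in the authors' deposited table. In the washout the members of this list had an estimated correlation of 0.636, against the preset 0.01, and the list did not pass camera with it. Its cameraPR p-value at 3 h can therefore be too small. The list shifts at 3 h, this one included, were also not separated from the trend of signs with exonic share. G2/M genes had 2 of 20 positive, Kif20a (0.83) and Mki67 (0.77) in the authors' deposited table (3 adjusted over the list alone, cameraPR adjusted p = 9.4e-06). G1/S genes had 1 of 21, Mcm4 (0.74, 5 adjusted over the list alone, cameraPR adjusted p = 0.000221), in the authors' deposited table. Besides ribosomal protein genes, 3 lists passed cameraPR at 3 h with 0 members called: the 2-cell-like state (20 of 20 signs positive, adjusted p = 0.000229), the aryl hydrocarbon receptor targets (7 of 8 positive, adjusted p = 0.0233, and 0.0598 with a mean count of at least 10) and the ERK feedback genes (2 of 12 positive, adjusted p = 0.00273). Adjusted over the list alone these had 0, 0 and 1 members past the threshold. The naive network member Dppa5a (1.05) and the mitochondrial mt-Co1 (0.78) were also positive in the authors' deposited table, without a shift of their lists (adjusted p = 0.413 and 0.137). At 3 h Ssrp1 was at 0.73 (adjusted p = 0.0507) there.

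At 6 h the highest genes with a mean count of at least 100 in the authors' deposited table were Nanos1, a germ cell RNA-binding protein (1.64), the kinase Plk3 (1.61), Trp53inp2 (1.59), Acap3 (1.52) and Ccn2 (1.51), and the lowest Fam83e (−1.55), the integrin Itga9 (−1.39), the chemokine receptor Ccr4 (−1.27), Adam23 (−1.26) and Enox1 (−1.26). Positive genes at 6 h had a median exonic share of 43.6%, against 16.8% in uncalled genes. Immediate early genes passed cameraPR (adjusted p = 0.000503) with 1 of 21 members called, Ccn2, and 7 adjusted over the list alone. Formative and primed genes also passed (adjusted p = 0.00415), with 2 of 21 positive, Lefty1 (1.55) and Sall2 (1.24) in the authors' deposited table, and 3 adjusted over the list alone. Histone genes passed with 1 of 64 positive, H3c13 (1.35) in the authors' deposited table, also 1 adjusted over the list alone (adjusted p = 0.0184). Ribosomal protein genes passed with 1 of 79 negative, Rps15a (−0.85) in the authors' deposited table, also 1 adjusted over the list alone (adjusted p = 0.0276). The 2-cell-like state passed with 0 of 19 called, also 0 adjusted over the list alone (adjusted p = 0.0216), and core factors with 1 of 6 negative, Zfp42, and 2 adjusted over the list alone (adjusted p = 0.0341, 0.140 with ranks and 0.0594 with a mean count of at least 10). From lists that did not pass, Paf1 of the PAF elongation complex (1.07), Atf5 (1.37) and Shmt2 (1.09) of the stress response, Dkk1 (1.52) and Hoxc13 (0.75) were positive in the authors' deposited table, and Chd2 (−1.0) of the chaperone list, the ERK inhibitor Spred1 (−0.79) and the p53 target Aen (−0.59) negative. Of the positive calls 82 of 214 were also positive at 12 h (17.8 expected of independent lists), and of the negative calls 146 of 174 were also negative (26.3 expected), an overlap computed after values were seen. The 3 h calls, compared likewise, shared 4 of 58 positive genes with 12 h (3.78 expected, odds ratio 1.06, Fisher's exact adjusted p = 0.79). Of the 5 negative ones 3 were shared (0.841 expected, adjusted p = 0.0728). Whether the tables of different times share libraries is not stated, so part of the excess over independent lists can come from shared ones.

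**Figure D1:**
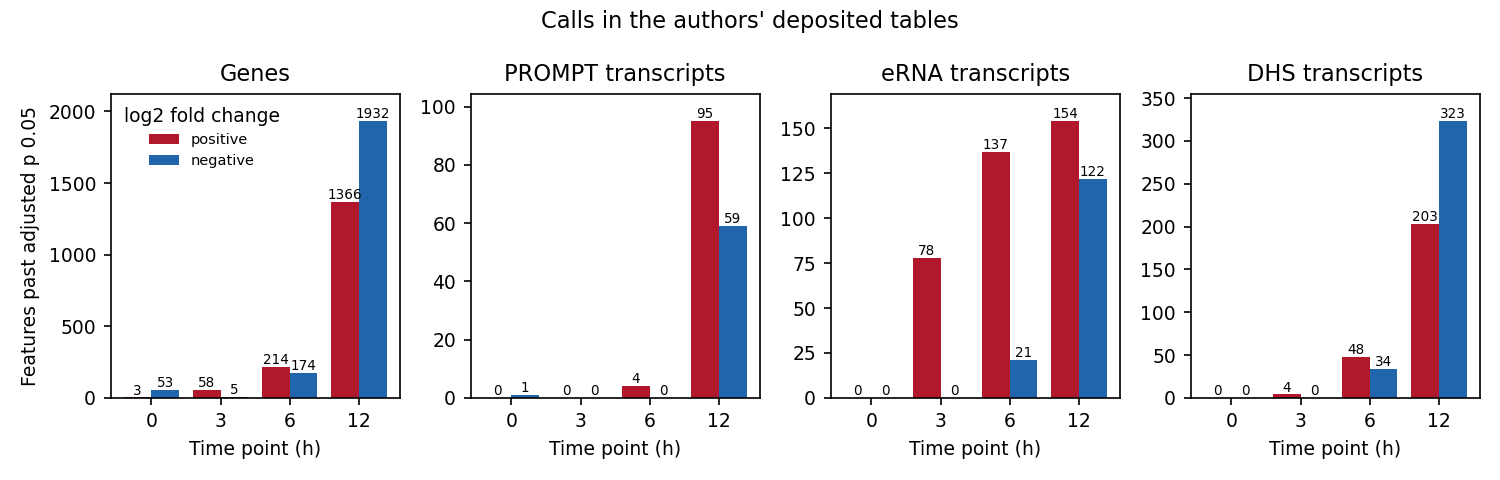
Number of features past adjusted p 0.05 in the authors' deposited tables, with positive (red) and negative (blue) calls as bars side by side, both rising from 0, for genes, PROMPTs, eRNAs and DHSs at 0, 3, 6 and 12 h. Gene calls number 56 at 0 h, 63 at 3 h, 388 at 6 h and 3298 at 12 h.

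The noncoding tables show whether transcription at promoters, enhancers and open chromatin moved over the same times. Enhancer transcripts had 78 positive and 0 negative calls at 3 h among 1440 with an adjusted p, 137 and 21 at 6 h among 2285, and 154 and 122 at 12 h among 6056, per the authors' deposited tables. The noncoding features named have a mean count of at least 50. ENH14701 (1.80 ± 0.45) and ENH14662 (1.77 ± 0.43) led at 3 h and ENH12598 (1.99) and ENH9964 (1.86) at 6 h, when ENH5499 (−1.19) and ENH14714 (−0.96) were lowest in the authors' deposited table. At 12 h the extremes in the authors' deposited table were ENH6562 (1.76), ENH14436 (1.75), ENH9266 (−2.46) and ENH550 (−2.13). DHSs had 4 positive and 0 negative calls at 3 h among 32517, led by DHS185339 (2.17 ± 0.37) and DHS36216 (1.88) in the authors' deposited table. At 6 h 48 were positive and 34 negative among 3530, led by DHS430 (1.77) and DHS85285 (1.77) against DHS190194 (−1.34) and DHS57778 (−1.34), in the authors' deposited table. The 203 positive and 323 negative DHS calls at 12 h, among 5638, included DHS111909 (2.32), DHS158357 (2.28), DHS167747 (−3.17) and DHS58375 (−2.93) in the authors' deposited table. PROMPTs had 0 calls at 3 h among 13088 (150 at an unadjusted p under 0.05), 4 positive at 6 h among 3292, and 95 positive and 59 negative at 12 h among 3052, per the authors' deposited tables. Those of Gm5493 (0.94), Gm24158 (−2.35) and 4933438K21Rik (−2.07) were the extremes above the count minimum in the authors' deposited table at 12 h. Of the PROMPTs positive at 12 h, 37 of 76 had a host gene with a positive sign, and of the negative ones 18 of 31 a negative sign. Host genes that were themselves called went the same way in 6 cases and the opposite way in 13 for positive PROMPTs. For negative PROMPTs the counts were 4 and 4.

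The 0 h tables come from before IAA, when the groups in the labels are untagged and SPT16-AID cells. Few genes differed: 3 were positive and 53 negative among 14909 genes in the authors' deposited table. Chrna4, an acetylcholine receptor subunit (2.06 ± 0.68, adjusted p = 0.0268), the imprinted gene Peg10 (1.28, adjusted p = 0.00272) and the galectin Lgals3 (1.12, adjusted p = 0.0119) were positive in the authors' deposited table. The most negative genes with a mean count of at least 100 were the Polycomb-related Scml2 (−2.63 ± 0.31, adjusted p = 9.13e-15), the Y-linked zinc finger Zfy1 (−2.54, adjusted p = 7.41e-08), the actin crosslinker Actn2 (−2.10), Tshz2 (−1.97) and Grap2 (−1.88) in the authors' deposited table, and from the lists Grhl2 (−1.70), mt-Nd6 (−1.24) and the Wnt effector Lef1 (−1.22). The 53 negative genes had a median exonic share of 7.78%, against 16.9% in uncalled genes. Both FACT genes and all 6 core factors had adjusted p of 1 in the authors' deposited table. Of the calls, 1 of 3 positive and 6 of 53 negative genes had the same call at 12 h (0.257 and 6.87 expected of independent lists, odds ratios 5.33 and 0.857, Fisher's exact adjusted p = 0.472 and 0.840). Among noncoding features at 0 h, per the authors' deposited tables, 1 PROMPT, that of mt-Nd5 (−1.85 ± 0.42, adjusted p = 0.00415), passed, and 0 eRNAs and 0 DHSs (84 and 151 at an unadjusted p under 0.05). By cameraPR with the preset correlation 11 lists passed at 0 h although 1 of their members, Lef1, was called and their shrunken medians were 0. Of these 10 were positive. The smallest adjusted p were those of the aryl hydrocarbon receptor targets (3.13e-07), histone genes (0.000147), the 2-cell-like state (0.000221) and G1/S genes (0.000659). The integrated stress response (0.00148), heat shock genes (0.00156, and 0.0547 with ranks), ribosomal protein genes (0.00258), p53 targets (0.0154), the naive network (0.0207, and 0.101 with ranks) and LIF/STAT3 targets (0.0428, and 0.0506 with ranks or 0.0676 with a mean count of at least 10) followed. Adjusted over the list alone, 2 aryl hydrocarbon receptor targets, 2 heat shock genes and 1 naive gene passed, and 0 members of the other positive lists. Wnt targets were negative (adjusted p = 0.0013, and 0.0755 with ranks, 3 genes adjusted over the list alone).

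The washout asks how nascent transcription stands 24 h after IAA was removed. Il31ra, a cytokine receptor gene on chromosome 13 (112519898 to 112594360), rose from 62.5 ± 6.76 to 879 ± 266 CPM (SD, n = 4 each), a log2 change of 3.81 ± 0.25 (SE, edgeR FDR = 4.46e-06). Ttll9, a tubulin ligase-like gene, rose from 0.792 ± 0.169 to 14.8 ± 2.40 CPM (4.19 ± 0.27, FDR = 4.46e-06). Slc16a3, which exports lactate, fell from 70.9 ± 33.5 to 9.12 ± 4.14 CPM (−2.99 ± 0.40, FDR = 0.00100), and Chac1 on chromosome 2 (119351229 to 119354381) fell from 26.9 ± 10.8 to 4.20 ± 2.88 CPM (−2.64 ± 0.42, FDR = 0.00224). Over 15110 tested genes, 1334 rose and 1149 fell in IAA libraries, 708 and 609 of them at least 2-fold, and all 2483 had the same sign in both lines. A fit over both lines together favours such genes, so this shared sign is not a replication between lines.

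Of genes with a mean logCPM of at least 2, predicted genes aside, the others with the highest log2 changes were Usp17le, a deubiquitinase of the 2-cell-like state on chromosome 7 (104768049 to 104777470, 4.99 ± 0.46, FDR = 4.25e-05), the secreted netrin Ntn4 (4.92 ± 0.58), the phospholipase Plch2 (4.28 ± 0.54) and the heparan sulfate sulfotransferase Hs3st4 (4.11 ± 0.51). The others with the lowest were the peptide hormone gene Adm2 (−3.0 ± 0.57, FDR = 0.00544), the secreted glycoprotein gene Creg2 (−2.68 ± 0.38), the thymic regulator Aire (−2.63 ± 0.40) and the vitamin C synthesis gene Gulo (−2.62 ± 0.35). For each of these 12 genes all 4 IAA libraries lay outside the range of the 4 EtOH libraries. Supt16, which encodes the degron target (chromosome 14, 52160414 to 52197416), stood at 77.5 ± 14.7 CPM in EtOH and 112 ± 16.7 in IAA libraries (0.53 ± 0.18, FDR = 0.0658), and Ssrp1 (chromosome 2, 85037234 to 85047109) at 37.6 ± 3.55 and 43.0 ± 3.88 (0.19 ± 0.15, FDR = 0.412). Of these FACT genes 1 of 2 passed adjusted over the list alone. Without the IAA library 11D_rep2 the Supt16 FDR was 0.0459. With library totals in place of TMM the log2 values were −0.10 (Supt16) and −0.42 (Ssrp1). Nanog stood at 139 ± 7.20 and 104 ± 14.4 CPM (−0.42 ± 0.15, FDR = 0.0801), Esrrb at −0.26 (FDR = 0.477), Pou5f1 at −0.15 (0.605), Zfp42 at −0.09 (0.762) and Klf4 at −0.02 (0.952). The core factors as a list did not pass camera (adjusted p = 0.376, 0 of 5 called, also 0 adjusted over the list alone).

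With library totals alone, the median of all tested genes moved from −0.05 to −0.66, 7855 genes passed and 433 (5.51%) of these were higher, against 53.7% with TMM, so all directions are relative to the TMM scale. In line 10E alone (2 against 2) 3366 genes passed, and in line 11D alone (2 against 2) 443.

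**Figure D2:**
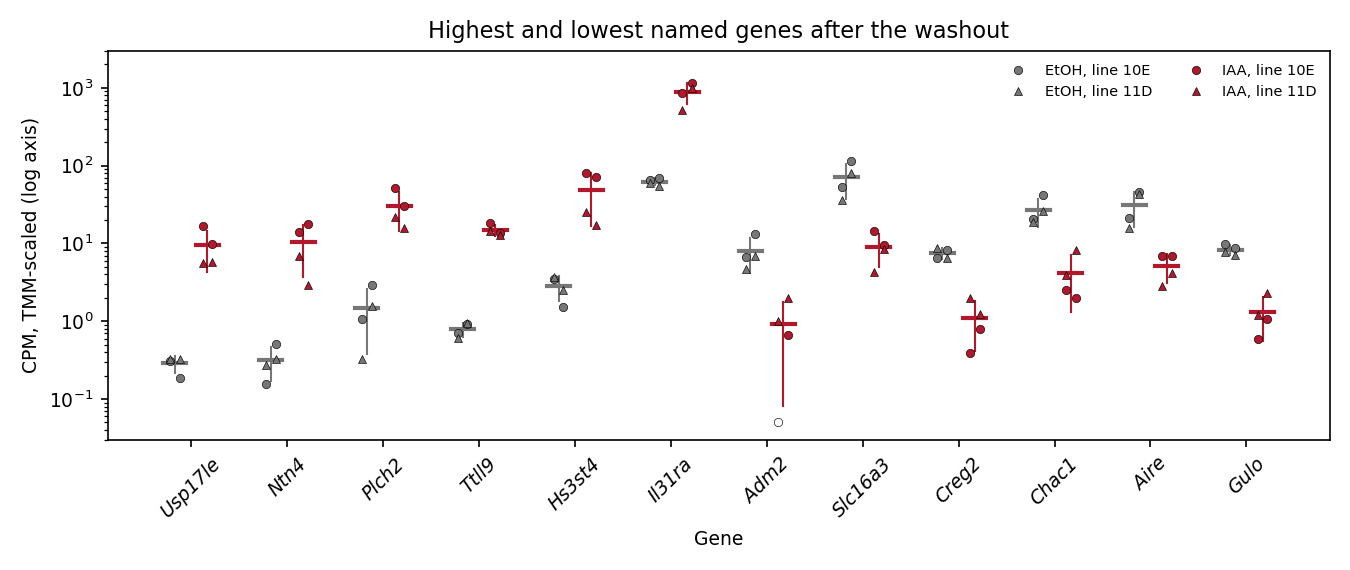
Normalised counts (CPM, log axis) of named genes in the 8 washout libraries, EtOH and IAA, with a point per library (circle 10E, triangle 11D) and a bar with whiskers for the mean ± SD (n = 4). Il31ra averages 62.5 CPM in EtOH and 879 CPM in IAA, and the open marker near the axis floor stands for 0 counts of Adm2 in IAA library 10E_rep1.

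By camera 7 fixed lists shifted in the washout, and 0 did with an estimated correlation. Ribosomal protein genes fell: 35 of 78 were lower and 0 higher (53 lower adjusted over the list alone), with a median of −0.62 (camera adjusted p = 2.23e-16, adjusted p = 0.470 with an estimated correlation, fry 0.0406). Rpl39 (−1.42), Rpl36a (−1.20), Rpl35 (−1.19) and Rpl37a (−0.94) had the smallest FDR, and line medians were −0.94 (10E) and −0.30 (11D). The median exonic share was 18.6% for all genes called lower, 14.3% for those called higher and 17.3% for uncalled genes. Median gene lengths were 18.6 kb for those lower, 35.9 kb for those higher and 24 kb for uncalled genes. The integrated stress response fell in 10 of 20 genes with 0 higher (13 lower adjusted over the list alone, median −0.68, camera adjusted p = 1.09e-06, adjusted p = 0.470 with an estimated correlation). It included Chac1, the gluconeogenic Pck2 (−1.43), the stress pseudokinase Trib3 (−1.28) and Aldh18a1 (−0.98). All 8 tested genes, of 21 members of the 2-cell-like state, rose (8 adjusted over the list alone, median 2.56, camera adjusted p = 3.47e-08, adjusted p = 0.300 with an estimated correlation), among them Usp17le, Usp17la (3.69), Zscan4d (2.83) and Tmem92 (2.28). With EtOH values near or below 1 CPM, members reach the count filter largely through their IAA values, so the other members stay untested. Without a filter the list passed as well (camera adjusted p = 2.19e-12). Histone chaperones and elongation factors had 9 of 26 higher and 0 lower (11 adjusted over the list alone, median 0.30, camera adjusted p = 2.69e-05, adjusted p = 0.300 with an estimated correlation). Ctr9 of the PAF complex rose by 1.54 ± 0.16 (FDR = 0.000153), the elongation factor Supt6 by 1.20, the remodeller Chd4 by 1.17 and Ep400 by 1.11.

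Heat shock genes had 4 of 14 higher (4 adjusted over the list alone, median 0.37, camera adjusted p = 0.0118, adjusted p = 0.300 with an estimated correlation): Hspa1a (3.29), Hspa1b (3.15), Hsph1 (1.04) and Hsp90ab1 (0.97). Targets of p53 had 8 of 26 higher and 0 lower (9 and 3 adjusted over the list alone, median 0.30, camera adjusted p = 0.00485, adjusted p = 0.490 with an estimated correlation, fry with the line block 0.0621). They included the death receptor Fas (3.76), the membrane protein Perp (3.51), the apoptosis gene Pmaip1 (2.91) and the kinase Plk2 (2.39). Replication-dependent histone genes had 12 of 54 higher (12 adjusted over the list alone, median 0.50, camera adjusted p = 0.000175, adjusted p = 0.681 with an estimated correlation, fry 0.303), such as H3c13 (1.20), H4c4 (1.17), H2bc11 (1.1) and H3c1 (1.05), with line medians of −0.16 (10E) and 0.98 (11D). Without both EtOH libraries numbered 1, which lay apart on the component with 20.2% of variance, the p53 and histone lists had camera adjusted p of 0.151 and 0.111, and without a count filter the p53, heat shock and histone lists had 0.103, 0.0947 and 0.0947. Without those 2 EtOH libraries Wnt targets (0.00365), G1/S genes (0.0225), ERK feedback genes and LIF/STAT3 targets (0.0317 each) passed on the higher side, as did the naive network and aryl hydrocarbon receptor targets (each just under 0.05).

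**Figure D3:**
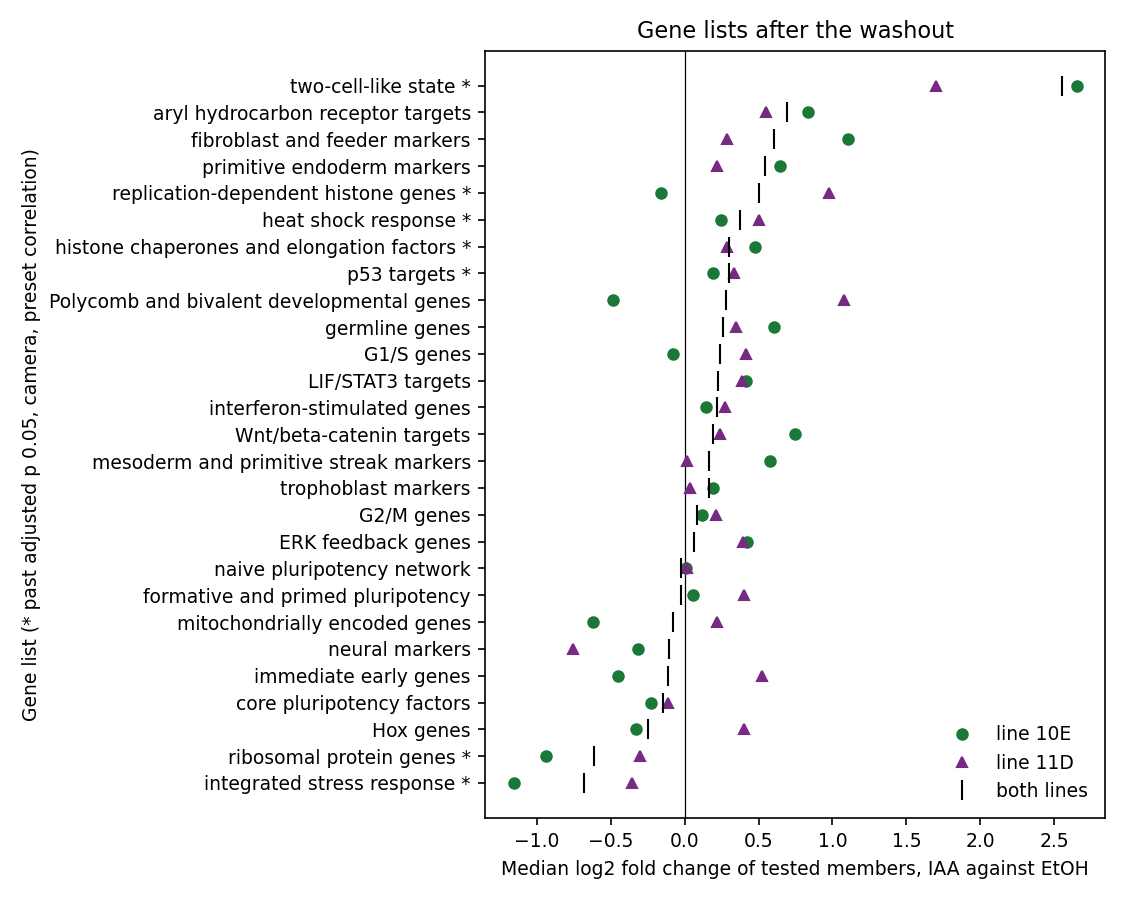
Median log2 fold change (IAA against EtOH, TMM scale) of the tested members of each gene list, with a circle for line 10E, a triangle for line 11D and a tick for both lines, where a star marks lists past camera with the preset correlation. Ribosomal protein genes lie below 0 in both lines (−0.94 and −0.30) and the 2-cell-like state above 0 (2.65 and 1.70).

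Lists of other cell types did not pass camera in the washout. By fry the primitive endoderm (adjusted p = 0.0314), fibroblast and feeder (0.0472) and formative and primed (0.0483) lists passed on the higher side. The other lists of this paragraph did not pass fry. Trophoblast markers had 0 of 9 called (adjusted p = 0.650), where Gata3 stood at 0.64 (FDR = 0.0750) and Krt18 at −0.85 (0.139). Primitive endoderm markers had 4 of 12 higher, the endocytic genes Cubn (2.18) and Dab2 (1.93) with Pdgfra (1.14) and Sparc (0.61) (adjusted p = 0.0727, 0.0396 with the line block, and with that block adjusted p = 0.356 with an estimated correlation). Mesoderm markers had 2 of 8 higher, Wnt3 (3.31) and Kdr (1.93), and 1 lower, Tbx6 (−1.30) (adjusted p = 0.376), and neural markers had 1 lower of 5, Map2 (−1.06), beside Stmn2 at −0.56 (adjusted p = 0.605). Fibroblast and feeder markers had 1 higher of 4, Vim (1.01), and Fn1 at 0.65 (FDR = 0.0565, list adjusted p = 0.166). The naive network had 1 higher and 2 lower genes of 29 (adjusted p = 0.723, median −0.02, mean 0.07 and test positive): the growth factor Fgf4 (−1.22) and Tcl1 (−0.86) fell and Stat3 (0.91) rose. Formative and primed genes had 5 of 18 higher, namely Wnt8a (4.17), the methyltransferase cofactor Dnmt3l (1.09), Etv4 (1.78), Grhl2 (1.1) and Dnmt3b (0.62) (adjusted p = 0.141, median −0.03, mean 0.38 and test positive). Adjusted over the list alone these 7 lists had 0, 4, 3, 1, 2, 3 and 6 genes. Tbx6, Pdgfra, Sparc, Etv4, Grhl2 and Dnmt3b were named after values were seen. Leaving out a single library ended the call of Vim (FDR 0.0612 without EtOH 10E_rep2 and 0.0653 without IAA 10E_rep1), of Stat3 (0.0644 to 0.0991 without EtOH 10E_rep2, EtOH 11D_rep2, IAA 10E_rep1 or IAA 10E_rep2) and of Map2 (0.0540 to 0.0800 without any library other than EtOH 10E_rep2 and IAA 11D_rep1).

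Among signalling lists, Wnt targets had 3 of 17 higher, Dkk1 (4.27), Nkd1 (0.78) and Rnf43 (0.75) (adjusted p = 0.141). Aryl hydrocarbon receptor targets had 3 of 5 higher, Cyp1a1 (3.54), Ahrr (1.76) and Tiparp (0.69) (camera adjusted p = 0.0727, fry adjusted p = 0.0406). With the line block the camera adjusted p of this list was 0.0396, and 0.356 with an estimated correlation. ERK feedback genes had Phlda1 (1.90) and Etv4 (1.78) higher and Spry1 (−1.1) lower of 12 (adjusted p = 0.221). Immediate early genes had Ccn1 (1.51), Junb (1.42) and Atf3 (1.14) higher and Klf10 (−0.91) lower of 18 (adjusted p = 0.723, median −0.11, mean 0.14 and test positive). LIF/STAT3 targets had 2 of 14 higher, Junb and Stat3 (0.91) (adjusted p = 0.166). Interferon-stimulated genes had 2 of 6 higher, among them Ddx58 (1.46) (camera adjusted p = 0.182, fry adjusted p = 0.0314). Germline genes had Piwil2 (2.08) and Ddx4 (1.83) higher and Stra8 (−2.14) lower of 11 (adjusted p = 0.158). Polycomb and bivalent genes had 1 lower of 5, Bmp7 (−0.88) (adjusted p = 0.798). G1/S genes had 1 of 21 higher, Mcm4 (0.67), with Orc1 at 0.60 (FDR = 0.0543). G2/M genes had 1 of 20, Kif11 (0.70), with Tpx2 at 0.58 (FDR = 0.0581). Both lists had adjusted p = 0.166. Hox genes had 2 of 9 higher, Hoxb9 (1.06) and Hoxc13 (0.84) (adjusted p = 0.605, median −0.25 and test positive). Mitochondrially encoded genes had 1 of 15, mt-Rnr1 at 2.61 (list adjusted p = 0.798, median −0.08, mean 0.26 and test positive), with mt-Rnr2 at 1.87 (FDR = 0.0659). Adjusted over the list alone the counts were 4 for Wnt targets, 8 for immediate early genes and as above for the other lists of this paragraph. Rnf43, Tiparp, Etv4, Atf3, Klf10 and Stra8 were named after values were seen. Leaving out IAA 10E_rep1 gave FDR 0.0544 for Mcm4, 0.0535 for Kif11, 0.0503 for Hoxc13, 0.0536 for Hoxb9, 0.0952 for Bmp7, 0.0991 for Stat3 and 0.0559 for Ddx58. Without IAA 10E_rep2 it was 0.0530 for mt-Rnr1, 0.0574 for Ddx58, 0.0537 for Kif11, 0.0749 for Bmp7 and 0.0677 for Stat3. Without EtOH 10E_rep1 it was 0.0537 for Kif11 and 0.0626 for Bmp7, and without EtOH 10E_rep2 0.0540 for Ddx58, 0.0653 for Kif11, 0.0893 for Bmp7 and 0.0856 for Stat3. In line 11D, single libraries ended the calls of Ahrr (0.0652 without IAA 11D_rep1), Stat3 (0.0644 without EtOH 11D_rep2) and Hoxb9 (0.0597 without EtOH 11D_rep1, 0.0669 and 0.0610 without IAA 11D_rep1 or 11D_rep2).

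The lines were compared because each is a separate SPT16-AID line. edgeR called 0 of 15110 genes with a response that differed between 10E and 11D (2250 at an unadjusted p under 0.05), and DESeq2 called 141 of 12473. In simulated libraries the edgeR interaction test recovered 0% of line differences of log2 1 and 19.7% of those of log2 2. Its 0 calls therefore do not show that the lines responded alike. Slc7a7, an amino acid transporter subunit, had the smallest adjusted p in DESeq2, with a log2 difference of −2.47 (11D minus 10E, adjusted p = 1.61e-06, edgeR FDR = 0.197). The noncoding RNA Bc1 (2.99, adjusted p = 0.00256) and the transcription factor Sox5 (−3.33, adjusted p = 0.00277) were among the next in DESeq2, all chosen after values were seen. Fold changes in the lines had a Spearman correlation of 0.463 across genes, which are not independent.

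Genes changed at 12 h were followed in the washout libraries, which are separate samples. Of 1122 genes positive at 12 h in the authors' deposited table and tested in both, 291 were higher in washout IAA libraries (99.7 expected of independent lists, odds ratio 4.47, Fisher's exact adjusted p = 6.24e-71) and 16 lower (80.7 expected). Of 1885 negative genes, 235 were lower (136 expected, odds ratio 2.12, adjusted p = 6.22e-19) and 12 higher (167 expected). As lists, the positive genes had a median washout log2 change of 0.38 (71.7% higher, camera adjusted p = 2.27e-12, adjusted p = 0.0968 with an estimated correlation) and the negative ones −0.18 (68.0% lower, camera adjusted p = 1.19e-05, adjusted p = 0.192 with an estimated correlation). Dkk1 stood at 4.52 in the authors' deposited table at 12 h and 4.27 in the washout, Plch2 at 4.35 and 4.28, Hspa1a at 4.27 and 3.29, Ntn4 at 2.62 and 4.92, Fas at 3.25 and 3.76, and Chac1 at −2.55 and −2.64. Ptgs2, the inducible prostaglandin synthase (5.06 in the authors' deposited table and 4.14), and the prostaglandin receptor Ptger3 (4.64 and 3.07) were chosen after values were seen. Esrrb and Zfp42, negative at 12 h, stood at −0.26 and −0.09 in the washout without passing. Without both EtOH libraries numbered 1 the negative list had a median of −0.09 (limma camera adjusted p = 0.0767), and the odds ratio of shared positive calls was 2.83, against 4.47. Across 12942 genes the log2 changes had a Spearman correlation of 0.258.

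**Figure D4:**
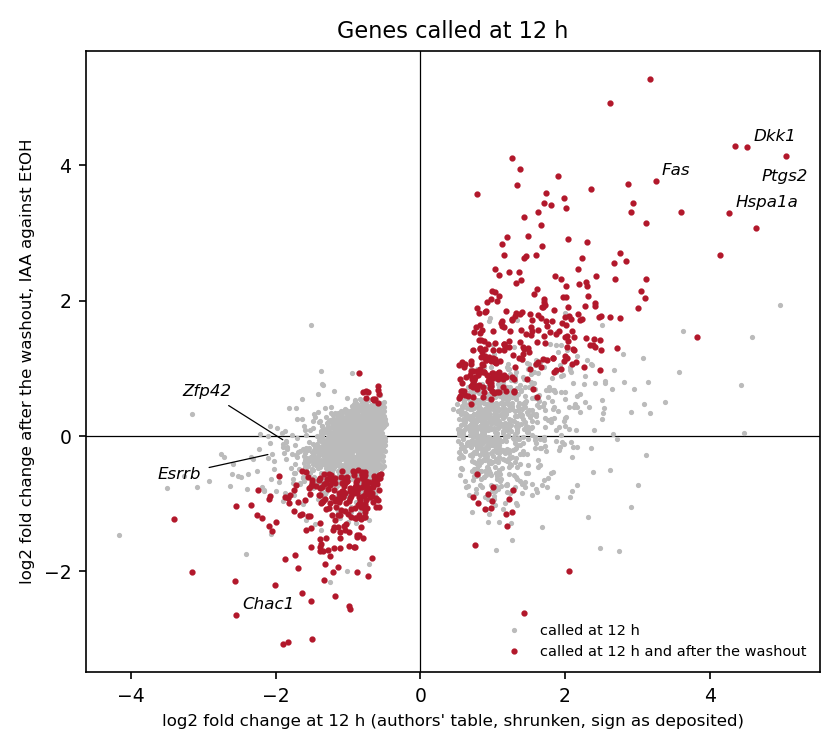
Shrunken log2 fold change at 12 h in the authors' deposited table (horizontal) against the washout log2 fold change of IAA over EtOH (vertical), a point per gene called at 12 h, in red where the gene was also called after the washout. Among genes positive at 12 h, 291 are higher and 16 lower in the washout.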

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

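Of the tests in this part, leaving out the 10 ribosomal RNA-like loci and leaving out both EtOH libraries numbered 1 were chosen only after the result was seen. The others were planned before theirs.

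Among 172 groups of 4 libraries (quality measures and named genes), 6 had a library far from the other 3, where chance gives about 8.6. The total count of IAA library 10E_rep1 was 6547992 against 10501187 to 10978586 in the other IAA libraries. The 10 ribosomal RNA-like loci took 30.6% of counts in IAA library 11D_rep1 (95% exact binomial interval 30.56 to 30.61%, counting error only) against 40.5 to 41.7% in the others. Ssrp1, a FACT subunit gene, was at 32.4 CPM in EtOH library 11D_rep2 against 38.6 to 39.8 CPM. Usp17le was at 0.185 CPM in EtOH library 10E_rep2 (others 0.309 to 0.330), Krt18 at 2.59 CPM in the same library (others 1.93 to 2.01), and Hoxb9 at 2.52 CPM in EtOH library 11D_rep1 (others 4.91 to 5.23). The response to IAA after washout differed between lines 10E and 11D at 141 genes by the DESeq2 likelihood ratio test, against 0 by edgeR (2250 at an unadjusted p under 0.05).

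The 2483 genes called between washout IAA and EtOH libraries came with 38.5% of IAA counts at ribosomal RNA-like loci and a lower depth elsewhere. Only 1 of the 35 splits of the 8 libraries into 4 and 4, the real one, called as many genes (highest other 202, and 0 among the other splits balanced over lines). Other groupings of these libraries thus gave far fewer calls. With 35 splits, and libraries not known to be separate cultures, chance is not excluded as the source. With EtOH libraries thinned to 6.0 M counts 91.0% of the calls kept their sign and call, so most calls do not need the greater EtOH depth. Thinning leaves the expected fold changes as they are. It therefore cannot show a bias within the IAA libraries that came with their lower depth, which stays open. Without the 10 loci 96.6% of the calls outside them kept their sign and call. TMM scaling already sets extreme genes aside, so that removal could hardly change the calls and decides nothing. Called higher genes had a median exonic share 4.22 points below that of called lower genes (difference −4.22). A permutation test of mean ranks, with genes taken as independent, gave p = 1e-05, the smallest it can give. The direction of this difference is opposite to a carry-over of unlabelled mature RNA into the IAA libraries. The share of ribosomal RNA-like loci, 9.85% in EtOH and 38.5% in IAA libraries, has the direction such a carry-over would give, so it stays open too. A carry-over in the EtOH libraries, which would raise the exonic share of lower genes, was not tested and also stays open. The median share was 18.6% in lower, 17.3% in uncalled and 14.3% in higher genes, so lower genes lay nearer to uncalled ones than higher genes did. The share of ribosomal RNA-like loci has the direction opposite to a carry-over in EtOH libraries. A lasting effect of SPT16 loss remains open, as do culture differences between treatments and an unlabelled day or batch behind the EtOH libraries numbered 1, which the labels do not give. Without those libraries 2441 genes passed, 1571 of them shared with the 2483.

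The 58 genes positive at 3 h, such as Hsp90ab1, Cd44 and Aqp3, had a median exonic share of 56.6%, against 15.8% in genes of the same mean count. The difference of 40.8 points (permutation p = 1e-04, the smallest they can give) is consistent with unlabelled mature RNA carried over in the libraries on the positive side. A high mean count alone is argued against, since 45.4% of uncalled genes of the same mean count had positive signs. Short length went with exonic share (median 5.61 kb against 28.8 kb in uncalled genes) and was not separated from it, and no biological explanation was tested.

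Of 1122 genes positive at 12 h, 291, such as Dkk1 and Fas, were also called higher in the washout and 16 lower, and of 1885 negative genes 235, such as Chac1, were called lower and 12 higher. Within 25 strata of expression and length the odds ratio of shared positive calls was 5.95 (95% interval 5.01 to 7.07), and within 10 strata of exonic share 4.93 (4.22 to 5.75), which argues against those properties as the whole source. Both intervals take genes as independent and leave out the spread between libraries, so they are too narrow. The negative calls had odds ratios of 3.87 and 2.27. A candidate explanation, found on the same data and not itself tested, is that part of the transcription changed by SPT16 loss stays changed in the recovery. The groups behind the 12 h table are not stated, so a response to IAA itself stays open.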

How the results depend on the processing

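Removal of the 10 ribosomal RNA-like loci, removal of both EtOH libraries numbered 1 and fry with the line block were chosen only after the results were seen. Of 1596 values for 80 named washout genes under the alternatives, 1434 kept direction and side of the threshold, 114 lost and 32 gained a call in the same direction, and 16 changed sign, 0 of them among genes called in the comparison itself. The cause was not tested for the values below, unless stated.

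The 2483 washout calls (1334 higher, 1149 lower) became 7855 (433 and 7422) with library totals, the scale having moved by construction, and 1467 (829 and 638) with line and replicate number as a block. FDR 0.01 left 778 (500 and 278). Line 10E alone gave 3366 (1758 and 1608) and line 11D alone 443 (279 and 164), each from 4 libraries. Lower calls were 1925 without a filter and 1835 at FDR 0.1. Leaving out single libraries gave 1415 to 2641 calls (799 to 1432 higher, 593 to 1209 lower). The count was 1415 (799 and 616) without IAA 10E_rep1 and 1555 without EtOH 10E_rep2 (593 lower), and 729 were lower without IAA 10E_rep2. RLE factors (2499), the CPM filter (2460), DESeq2 (3277), removal of mitochondrial and ribosomal RNA genes (2489) or of the 10 loci (2508) stayed within 1.5 times.

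Lists past the test numbered 7 with camera, 0 with an estimated correlation, 11 with fry, 4 without a filter (p53 targets 0.103, heat shock genes and histone genes 0.0947), 15 with library totals, 11 without both EtOH libraries numbered 1 and 7 to 9 with single libraries left out. The line difference had 421 calls without a filter and 141 with DESeq2, against 0.

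Signs changed with library totals for Supt16 (−0.10), Ssrp1 (−0.42), Orc1 (−0.021) and Tpx2 (−0.053), and without both EtOH libraries numbered 1 for Pou5f1 (0.045), Klf4 (0.25) and Esrrb (0.24). Klf4 was also at 0.006 with RLE factors, 0.006 with DESeq2, 0.026 in line 10E alone, 0.003 without the 10 loci. It ran from −0.162 to 0.131 with single libraries left out, above 0 without EtOH 10E_rep1 (0.131), IAA 11D_rep1 (0.113) or IAA 11D_rep2 (0.003). Zfp42 ran from −0.157 to 0.008 (without IAA 10E_rep1) and was at 0.030 in line 11D alone. None of these genes was called.

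The authors' deposited tables had 32, 2, 102 and 1918 genes at 0, 3, 6 and 12 h at adjusted p 0.01, and 20, 132 and 1710 at 3, 6 and 12 h with at least a 2-fold change. Enhancer transcripts numbered 31 (3 h), 49 (6 h) and 66 (12 h) at adjusted p 0.01 and 47 at 3 h with 2-fold, PROMPTs 1 (6 h) and 44 (12 h), and DHSs 28 (6 h) and 238 (12 h). Rank-based cameraPR passed 7 lists at 0 h, against 11. The median washout change of genes negative at 12 h was −0.089 without both EtOH libraries numbered 1 (limma camera adjusted p = 0.0767), and the odds ratio of shared positive calls 2.83 against 4.47. The 0 h against 12 h odds ratios became 0 (positive) and 1.77 (negative) at adjusted p 0.01 in both, from very few shared genes.

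With line as a block, 2302 genes were called (1228 higher, 1074 lower), 2226 of them shared, and primitive endoderm markers and aryl hydrocarbon receptor targets passed camera (0.0396 each, and 0.356 each with an estimated correlation); no other list call changed. The labels do not say whether libraries with the same replicate number within a line were handled together. Their deviations had correlations of 0.345, −0.497, −0.315 and −0.027, without a common sign, which cannot settle it. The block of line and number (1467 calls) is therefore given as an alternative and not read as pairing. No paired analysis was possible because, for the time course, the tables hold no libraries; the planned block there was not run. In simulated libraries edgeR recovered 1.49% of genes changed by log2 0.5. It called 104 genes there, against 2483 in the washout, and with fewer calls the false discovery rate sets a stricter p-value cutoff. That recovery therefore does not tell how often small changes are called in the washout. Of the washout calls, 708 higher and 609 lower genes changed at least 2-fold, and the rest changed less.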

Other observations

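The test of hypoxia genes was chosen only after Slc16a3 and Bnip3 were seen to be low, before its own result was seen, and the test of X- and Y-linked genes only after the 0 h calls were seen. The rest of this part is values only.

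Genes that cells switch on when oxygen is scarce lay on the lower side in washout IAA libraries. Of 22 tested hypoxia-induced genes 6 were lower and 1 higher (median −0.32; limma camera p = 0.00508, fry p = 0.00679; p = 0.0963 with an estimated correlation), with line medians of −0.32 (10E) and −0.43 (11D). The angiogenic factor Vegfa (−1.21; edgeR FDR = 0.00905), the stress gene Ndrg1 (−1.24; FDR = 0.0140), Ankrd37 (−1.85), the lactate-producing enzyme Ldha (−0.75; FDR = 0.0124), the oxygen sensor Egln1 (−0.75) and Mxi1 (−0.59) fell, and the demethylase Kdm3a (0.54) rose. This median of −0.315 is consistent with EtOH cultures having been closer to oxygen limitation than IAA cultures. This is a hypothesis, and the call is lost with an estimated correlation.

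At 0 h, 6 X-linked and 3 Y-linked genes were among the 53 negative genes of the authors' deposited table, more than the 522 genes on those chromosomes among 14909 would give (odds ratio 5.72; Fisher's exact adjusted p = 0.000827). Among them Scml2 (X), Nxf3 (X) and Zfy1 (Y) stood in the authors' deposited table at −2.63, −4.95 and −2.54, all chosen after values were seen. At 6 h positive genes also had a high median exonic share, 43.6% against 16.8% in uncalled genes. In 5 equal bins of genes by exonic share at 3 h, the share of positive signs was 17, 28.5, 45.7, 62.9 and 84.7% from lowest to highest.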
